A study of Homo sapiens with 12 samples.

How the data were processed

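Polyadenylated RNA from Cal27 and Detroit 562 cells, each transfected with a control siRNA or a THBS1 siRNA, had been sequenced as stranded messenger libraries, with 3 replicates in each of 4 groups. The deposited values are expected counts, that is, estimated counts per gene that the authors made with RSEM, whole numbers in the table and not scaled for library size. The deposited table also holds an Entrez identifier per gene, which is not a measurement. Per the labels, the authors trimmed reads with fastp 0.23.4, aligned them with STAR 2.7.9a to GRCh38 and counted them with RSEM 1.3.1. The annotation release, the rule by which 15452 genes entered the table and whether counting used the strand are not given in the sources used here. Symbols came from an Ensembl identifier table, which named 15425 of the genes and left 27 without a symbol, and coordinates and messenger sequences came from GENCODE release 29.

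Total counts were 20386860 to 37229672 in 11 libraries and 789227 in Detroit 562 control replicate 2. The floor of detection was set at 3 counts, and intervals and floors cover counting error only, since reads were not marked as single molecules. In the 11 deeper libraries the floor is 0.0806 to 0.147 CPM (counts scaled by library size), and in the shallow library 3.80 CPM.

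Differential expression was tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr by group (minimum count 10, minimum total count 15), which left 13346 and took out 2106. Libraries were scaled by TMM, and all 12 were fitted together with 1 mean per group, which leaves 8 residual degrees of freedom. Quasi-likelihood F tests were made for THBS1 siRNA against control in each line, for the difference between these effects (Detroit 562 minus Cal27) and for the control libraries of Detroit 562 against those of Cal27. The p values were adjusted by Benjamini-Hochberg within each comparison and called under 0.05. The SE of a log2 fold change was taken as its size divided by the square root of F. Fitted log2 fold changes of genes with no count in a group were not used as bounds; these were computed from the summed counts with a floor of 3 counts over the group, and ratios with 1 to 3 counts have a 95% counting interval.

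In all 31 gene lists, the tests and the rule for named genes were fixed before the data were examined. The rule took THBS1, the 8 genes raised and the 8 lowered most in each comparison among called genes with at least 5 CPM in the higher group and no overlap between the arms, the 8 most raised and 8 most lowered in both lines, and up to 4 called members of each list that was called or had at least 3 called members. Lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. List tests without THBS1 in its list were added after the data had been seen. Of the list tests called at the preset correlation, that of EGFR ligands and MAPK feedback genes for the difference between the lines was the one also called with an estimated correlation. Counts called over each list's own members are given as adjusted over the list alone. Overlap between the lines was tested with Fisher's exact test over the genes tested, one-sided.

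Sequences of 7 bases in 3′ UTRs were examined for 12986 tested genes with an annotated 3′ UTR of at least 50 bases. Only the principal protein-coding transcript of each gene was searched, or, where several or none were so marked, that with the longest 3′ UTR. A gene said to hold no sequence may therefore hold it in another transcript. Each of 16194 sequences found in at least 50 of these genes was tested in a regression of the log2 fold change, limited to 2 in size, on its presence, with UTR length, GC content and expression as covariates, and the extreme t values were set against 100 permutations of the fold changes. Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used. Where a named gene shares at least 20% of its exon sequence with other genes, or overlaps others on the opposite strand over at least 20%, by stretches of 50 bases, the share is given and its value is uncertain. That limit was chosen after the shares were seen, and smaller shares are not given.

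The fit was tested on simulated data with planted changes at the spread of these libraries. At 2-fold it recovered 92% of the planted genes in Cal27, 96% in Detroit 562, 76% for the difference between the lines and 88% between the lines. At 1.25-fold it recovered 68%, 64%, 36% and 56%. False calls were counted over all calls of a comparison and not by fold, and made up 6.11%, 7.78%, 9.21% and 6.36% of these. Camera called 2 of 2 shifted lists and also 1 list that had not itself been shifted, apoptosis regulators, which holds members of both shifted lists. The simulated genes varied independently, so that this does not test camera where the genes of a list are correlated. A planted 7-base sequence ranked first in 10 of 10 rounds at each of 3 shifts.

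Alternatives were DESeq2 size factors, upper-quartile factors, no filter on low counts, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, unrounded counts (the same fit here, since the counts were whole, and left out of the tallies), only the libraries compared, replicate number as a block and each library left out in turn. Fits without the shallow library together with Cal27 THBS1 siRNA replicate 2, whose library name carries another lane code, were added after the data had been seen. The labels do not say that replicate numbers mark a shared day, so no block entered the comparisons reported. Across arms, residuals of libraries with the same number had r of -0.23, 0.05 and 0.47 in Cal27. In Detroit 562 they had r of -0.08, -0.13 and -0.13, so that pairing is left open for Cal27 replicate 3. Variants, splicing and single transcripts were not analysed here.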

Results

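Messenger RNA was sequenced from 12 cultures of established human head and neck squamous carcinoma lines that the labels describe as radioresistant. Cal27 is a tongue carcinoma line and was grown in DMEM, and Detroit 562 is a pharyngeal carcinoma line and was grown in EMEM. Each line received 10 nM of a control siRNA or of an siRNA against THBS1, with 3 biological replicates in each of the 4 groups. The 11 deeper libraries held 20386860 to 37229672 counts. Detroit 562 control replicate 2 held 789227 counts, so that the median of the other libraries was 29.7 times its total. In that library 3 counts, taken as the floor of detection, corresponded to 3.80 CPM (counts scaled by library size), against 0.0806 to 0.147 CPM in the others. The first principal component carried 83.0% of the variance and separated the lines, the second carried 12.3% and set the shallow library apart, and the third carried 1.11% and followed the siRNA. All values below are means with the standard deviation (SD, n = 3) or log2 fold changes with the standard error (SE) of the edgeR quasi-likelihood fit. Adjusted p values are from the edgeR quasi-likelihood F test with the Benjamini-Hochberg correction over 13346 genes, and a gene was called at an adjusted p under 0.05. Camera was used to test each of 31 gene lists against all other genes, and a directional fry test asks only whether the genes of a list moved on balance one way.

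The first question was how far the THBS1 messenger was lowered by its siRNA. THBS1 (ENSG00000137801, GRCh38 chromosome 15, 39581079 to 39599466, plus strand) encodes thrombospondin-1, a secreted matrix glycoprotein that binds CD36, CD47 and integrins and activates latent TGF-beta. In Cal27 its level fell from 1119 ± 61.5 CPM to 180.5 ± 1.33 CPM, which left 16.1% of the control level (log2 fold change -2.63 ± 0.048 SE, adjusted p = 1.41e-26). In Detroit 562 it fell from 2208 ± 79.3 CPM to 346.1 ± 2.51 CPM, which left 15.6% (-2.68 ± 0.048 SE, adjusted p = 8.38e-27). The knockdown did not differ detectably between the lines (difference -0.05 ± 0.064 SE, adjusted p = 0.917). With control siRNA, THBS1 was 1.98-fold higher in Detroit 562 than in Cal27 (log2 0.99 ± 0.045 SE, adjusted p = 2.68e-18).

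**Figure D1:**
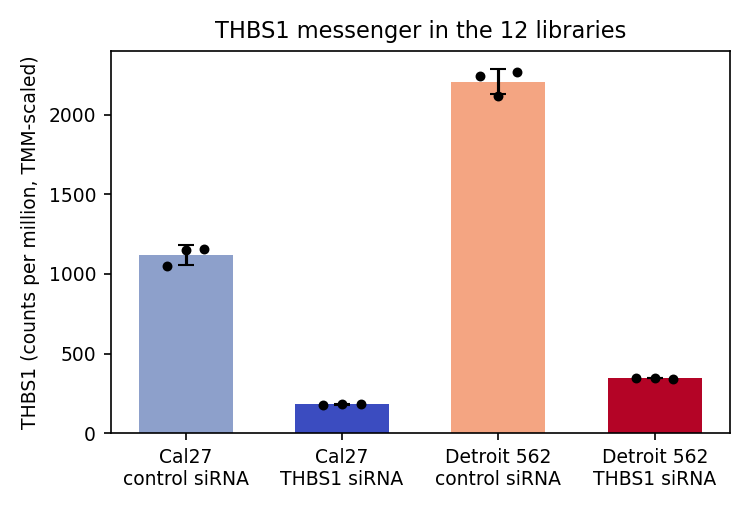
THBS1 messenger level in CPM (vertical axis, from 0) in each of the 4 groups. Bars are means, error bars are SD over 3 replicates and points are single libraries. The control libraries lie at 1048 to 1156 CPM in Cal27 and 2117 to 2265 CPM in Detroit 562, and the knockdown libraries at 179 to 182 CPM and 343 to 348 CPM.

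The next question was which genes responded to THBS1 siRNA in both lines. The RNA helicase and splicing factor gene DDX46 (ENSG00000145833, chromosome 5, 134758771 to 134855133) fell by 1.33 ± 0.049 SE on the log2 scale in Cal27 and by 1.43 ± 0.051 SE in Detroit 562. TGFB2 (ENSG00000092969, chromosome 1, 218346235 to 218444619), which encodes the ligand TGF-beta-2, fell by 1.33 ± 0.074 SE and by 1.04 ± 0.058 SE. FGFBP1, whose product is a secreted carrier that releases fibroblast growth factors from the matrix, fell by 1.00 ± 0.051 SE and by 0.99 ± 0.049 SE. The actin-binding tropomyosin gene TPM4 (ENSG00000167460, chromosome 19, 16067021 to 16103005) rose 2.27-fold in Cal27, from 166.6 ± 7.40 to 378.7 ± 0.997 CPM, and 2.54-fold in Detroit 562, from 238.5 ± 9.57 to 613.6 ± 16.2 CPM.

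Other genes that fell in both lines were the cholesteryl ester hydrolase gene NCEH1 (log2 fold change -1.02 in Cal27 and -0.94 in Detroit 562), the transcription elongation and splicing factor gene HTATSF1 (-0.92 and -1.21), the mitochondrial micropeptide gene MTLN (-1.02 and -0.88) and LIFR, the receptor gene of leukaemia inhibitory factor (-0.92 and -0.85). Those that rose in both included the endosomal syntaxin gene STX12 (1.07 and 1.06), the cyclin-dependent kinase gene CDK14 (1.23 and 1.04), the opioid growth factor receptor gene OGFR (1.04 and 0.98), the G-protein regulator gene RGS19 (0.94 and 1.12), the dynein adaptor gene BICD2 (0.93 and 1.05) and the dermatan sulfotransferase gene CHST14 (0.93 and 1.15). The largest adjusted p among these genes and THBS1 was 3.94e-08, for MTLN in Detroit 562. TPM4 shares 22.9% of its exon sequence with a pseudogene and TGFB2 26.9% with the overlapping TGFB2-OT1, so that their values are uncertain. In all, 440 genes rose in both lines, against 48.4 for independent lists, and 305 fell in both, against 26.1 (Fisher's exact test, one-sided, p = 1.28e-281 for the fallen genes). That test takes genes as independent, and both call lists came from 1 fit, so that its p value does not measure the spread between replicates. With upper-quartile scaling 381 rose and 388 fell in both, so that the excess of shared raised genes depends on the scaling. Genes called in both lines went in opposite directions in 5 of 750 cases, against 71.7 for independent lists. These were MAFF, SEMA7A, PHLDA1, MT-ND5 and MT-ND6, of which the last pair was named after its values were seen and was called in neither line by DESeq2. Across genes, which are not independent replicates, the fold changes of the lines had a Pearson r of 0.598 over the 2046 genes called in either line and 0.176 over all genes tested. Without Detroit 562 control replicate 1, 493 genes were shared in place of 745.

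**Figure D2:**
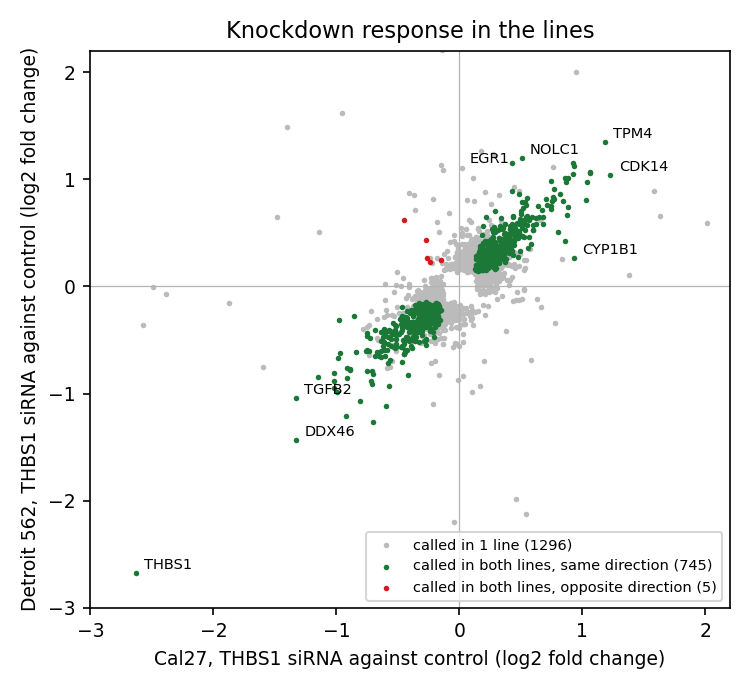
Log2 fold change after THBS1 siRNA in Cal27 (horizontal axis) and Detroit 562 (vertical axis) for genes called in at least 1 line. Green points are the 745 genes called in both lines in the same direction, red points the 5 called in opposite directions and grey points genes called in 1 line. THBS1, DDX46, TGFB2 and TPM4 lie far from the origin along the diagonal, and 8 called genes lie outside the axes.

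Genes that fell in both lines often shared short sequences in their 3′ untranslated region (UTR). The sequences were picked from 16194 by their tie to these same fold changes. Their shares therefore describe that choice and are no separate test, and they were not adjusted for UTR length. The 7-base sequence AAGACTA or AGACTAA was present in 153 of the 304 fallen genes other than THBS1, or 50.3% (95% Wilson interval 44.7 to 55.9%), against 10.7% of the risen genes and 13.3% of the 12986 tested genes with an annotated 3′ UTR. Of the 7 named fallen genes, TGFB2, FGFBP1, NCEH1 and LIFR held these sequences or the related pair ACAACGA and CAACGAA, and DDX46, HTATSF1 and MTLN did not. TCGGAGA or CGGAGAA was present in 77 of 431 risen genes, or 17.9% (14.5 to 21.8%), against 1.64% of the fallen genes and 3.55% of all. TPM4, CDK14, BICD2 and CHST14 held at least 1 of that pair, while STX12, OGFR and RGS19 held neither.

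**Figure D3:**
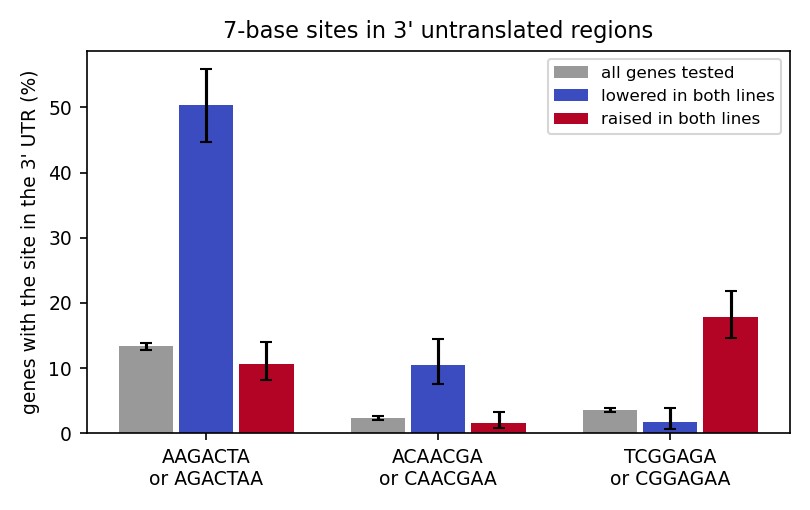
Share of genes whose 3′ UTR holds at least 1 of a pair of 7-base sequences (vertical axis, percent, from 0), for all genes tested, genes lowered in both lines and genes raised in both lines. The sequences were chosen from these same fold changes. Error bars are 95% Wilson intervals over genes; 50.3% of the lowered genes held AAGACTA or AGACTAA and 17.9% of the raised genes held TCGGAGA or CGGAGAA.

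Within Cal27, the comparison asked which genes and gene groups changed after THBS1 siRNA. Besides the genes already named, large falls were those of the HSP90 cochaperone gene CHORDC1 (-1.15 ± 0.048 SE, adjusted p = 6.64e-17) and of HMGA2, which encodes a chromatin architectural factor (-1.02 ± 0.060 SE, adjusted p = 1.45e-13). CHORDC1 held AAGACTA and AGACTAA in its 3′ UTR, and HMGA2 held ACAACGA and CAACGAA. The neuronal kinase gene LMTK3 rose (1.03 ± 0.094 SE, adjusted p = 1.88e-09). F3, the gene of tissue factor, fell (-0.98 ± 0.044 SE, adjusted p = 1.07e-16), and SDC4, a heparan sulfate receptor gene for thrombospondin-1, rose (0.54 ± 0.045 SE, adjusted p = 4.29e-11). The read-through gene TVP23C-CDRT4 rose by 1.38 and CDRT4 changed by -1.14, but these share 98.3% and 90.2% of their exon sequence, mostly with each other, so that their values are uncertain. CDRT4 also lost its call without Cal27 control replicate 1 (adjusted p = 0.0647), and TVP23C-CDRT4 in 1 alternative fit (adjusted p = 0.0565). In all 1331 genes were called, 722 higher and 609 lower, of which 26 changed at least 2-fold. The calls were 656 higher and 745 lower with upper-quartile scaling and 616 and 765 with no low-count filter, so that the direction of the excess depends on the processing.

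Among targets of YAP and TAZ, the coactivators held back by the Hippo pathway, 9 of 27 measured genes fell and 1 rose in Cal27, or 11 and 1 adjusted over the list alone. Those that fell included F3, TGFB2, the secreted kinase-related gene FJX1 (-0.53) and the receptor tyrosine kinase gene AXL (-0.24). F3 and TGFB2 held AAGACTA and FJX1 held ACAACGA in the 3′ UTR, while AXL held none of the 4 sequences found in lowered genes. The list was lower as a whole (camera adjusted p = 6.51e-11, and adjusted p = 0.0871 with an estimated correlation). Of 42 genes of G2/M and mitosis, 5 fell and 2 rose, or 11 and 2 adjusted over the list alone, and the list was lower (adjusted p = 0.00104, and adjusted p = 0.472 with an estimated correlation). The kinetochore gene NDC80 fell by 0.25 and the spindle checkpoint gene MAD2L1 by 0.26. MAD2L1 held AGACTAA in the 3′ UTR, and NDC80 held none of the sequences found in lowered genes. Of 26 angiogenesis genes, 4 fell and 1 rose, or 4 and 2 adjusted over the list alone (list lower, adjusted p = 0.0411, and adjusted p = 0.472 with an estimated correlation). The matrix metalloproteinase inhibitor gene TIMP3 fell by 0.61 and the Notch ligand gene JAG1 by 0.22. Among 17 thrombospondins and receptors, SDC4 and SDC1 (0.25) rose and THBS1 and CD47 (-0.15) fell, or 4 rose and 2 fell adjusted over the list alone. The call of CD47 was lost without Cal27 control replicate 1 or 2 or THBS1 siRNA replicate 2 or 3, with an adjusted p of up to 0.155. That list was lower by camera (adjusted p = 0.0303, and adjusted p = 0.194 with an estimated correlation), but THBS1 itself made it so. Without THBS1 the other 16 genes were not called by camera (adjusted p = 0.0931, median log2 fold change 0.06) and were higher by fry (adjusted p = 0.00186), and the angiogenesis list then lost its camera call (adjusted p = 0.0548).

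The other lists were not called by camera in Cal27. The directional fry test called 6 of them, namely TGF-beta response (adjusted p = 0.00886), p53 targets (0.0169), interferon-stimulated genes (0.00886), lipid synthesis (0.0243) and EGFR ligands and MAPK feedback (0.0142), all lower, and apoptosis regulators (0.0216), higher. Of 30 TGF-beta response genes, 3 rose and 3 fell, or 3 and 4 adjusted over the list alone; the type IV collagen gene COL4A1 fell by 0.89. Matrix and integrin genes gave 1 risen and 5 fallen of 38 (2 and 5 adjusted over the list alone), including the collagen lysyl hydroxylase gene PLOD2 at -0.30. Mesenchymal transition genes gave 4 risen and 3 fallen of 27 (5 and 3), with the collagenase gene MMP13 at 0.37. The desmoglein gene DSG2 (-0.17) was the 1 called of 30 epithelial junction genes (0 adjusted over the list alone), and the keratin genes KRT15 (0.39) and KRT13 (0.20) rose among 33 of squamous differentiation (2 adjusted over the list alone). The calls of DSG2 and KRT13 were lost without Cal27 control replicate 2 or THBS1 siRNA replicate 3, and that of KRT13 also without control replicate 3 or THBS1 siRNA replicate 1, with adjusted p of up to 0.138 and 0.148. Among DNA repair genes, the MRN complex gene RAD50 (-0.26) fell of 40 for homologous recombination (1 adjusted over the list alone), but 90.6% of its exon sequence is also annotated in another gene. Of 40 end joining and damage signalling genes, 1 rose and 5 fell (2 and 5), with the ubiquitin ligase gene RNF168 at -0.29. Of 34 base, nucleotide and mismatch repair genes, 2 rose and 1 fell (2 and 1), with the thymine DNA glycosylase gene TDG at 0.36. The p53 targets CCNG1 (-0.59) and PLK2 (-0.44) fell of 31 (2 adjusted over the list alone). Of 39 G1/S genes, 1 rose and 3 fell (1 and 3), with the cyclin gene CCND1 at -0.36 and the ribonucleotide reductase gene RRM2 at -0.29, although RRM2 shares 31.2% of its exon sequence with an overlapping gene. Of the fallen genes named in these lists, COL4A1, PLOD2, DSG2 and RRM2 held at least 1 of the 4 sequences found in lowered genes. RAD50, RNF168, CCNG1, PLK2 and CCND1 held none. At least 1 was held by 57.6% of the genes lowered in both lines and 15.0% of all tested with a 3′ UTR.

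Interferon-stimulated genes in Cal27 gave 4 fallen of 46 (4 adjusted over the list alone), with IFIT3, an antiviral tetratricopeptide gene, at -0.31. No antigen presentation gene of 27 was called by edgeR or by DESeq2, with 3 at an unadjusted p under 0.05 (0 adjusted over the list alone). NF-kappaB and cytokine genes gave 2 risen and 2 fallen of 38 (2 and 2 adjusted over the list alone). These 4 calls, of IL6, CXCL1, SOD2 and TNFAIP3, were each lost in at least 1 fit that left out 1 library (adjusted p up to 0.19). IL6 overlaps an antisense gene over 22.4% of its exons, so that its value is uncertain. DESeq2 called 1 member of that list. Hypoxia and glycolysis genes gave 3 and 1 of 42 (3 and 1), and NRF2 targets 3 and 4 of 39 (5 and 4). In the last group the malic enzyme gene ME1 rose by 0.48 and the thioredoxin reductase gene TXNRD1 fell by 0.24. Unfolded protein and stress response genes gave 6 risen and 1 fallen of 40 (7 and 2), with the pseudokinase gene TRIB3 at 0.34 and the chaperone gene DNAJC3 at -0.43. Of 34 lipid synthesis genes, 2 rose and 1 fell (2 and 1); the fatty acid elongase gene ELOVL6 fell by 0.89. EGFR ligand and MAPK feedback genes gave 1 risen and 6 fallen of 27 (2 and 7), with the receptor gene EGFR at -0.22. Components of PI3K, AKT and mTOR signalling gave 1 risen and 4 fallen of 31 (1 and 5), with the regulatory subunit gene PIK3R3 at -0.45. Apoptosis regulators gave 5 risen and 2 fallen of 36 (6 and 4). The Notch receptor genes NOTCH1 (0.21) and NOTCH3 (0.19) rose of 21 stemness genes (2 adjusted over the list alone). Of 22 canonical histone genes 1 rose and 2 fell (1 and 3), of 20 immediate early and heat shock genes IER2 rose (0.51; 1 adjusted over the list alone), and of 13 mitochondrially encoded messengers MT-ND5 (-0.26) and MT-ND6 (-0.24) fell (2 adjusted over the list alone). Without Cal27 control replicate 1, or without THBS1 siRNA replicate 2 or 3, the calls of NOTCH1, NOTCH3, MT-ND5 and MT-ND6 were lost in 2, 3, 2 and 2 of the 6 fits that left out 1 library, with adjusted p of up to 0.0777, 0.121, 0.0694 and 0.290. In the 3′ UTR, the fallen genes TXNRD1, DNAJC3, ELOVL6, EGFR and PIK3R3 held at least 1 of the sequences found in lowered genes, and IFIT3 held none. Called genes of lists with fewer than 3 calls were named after their values were seen.

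In Detroit 562 the same comparison gave further genes that rose or fell more than 2-fold. NOLC1, which encodes a nucleolar chaperone of small nucleolar ribonucleoproteins, rose from 98.4 ± 15.3 to 242.1 ± 6.90 CPM, a fitted 2.30-fold change (log2 1.20 ± 0.054 SE, adjusted p = 3.87e-16), where the shallow control library, at 81.3 CPM, lowers the control mean. RBM28, a spliceosomal and nucleolar RNA-binding protein gene, fell by 1.26 ± 0.068 SE (adjusted p = 1.82e-14), and the cap-binding complex gene NCBP1 fell by 1.12 ± 0.053 SE (adjusted p = 1.36e-15). EGR1 (ENSG00000120738, chromosome 5, 138465490 to 138469315), an immediate early transcription factor gene, rose 2.16-fold from 4.76 ± 0.180 to 10.1 ± 0.447 CPM (log2 1.11 ± 0.104 SE, adjusted p = 3.85e-09), and the leucine-rich repeat gene ELFN2 rose 2.22-fold (1.15 ± 0.106 SE, adjusted p = 2.54e-09). NOLC1 and ELFN2 held at least 1 of TCGGAGA and CGGAGAA in the 3′ UTR, and RBM28 and NCBP1 held none of the sequences found in lowered genes. In all 1465 genes were called, 894 higher and 571 lower, and 31 of them changed at least 2-fold. With upper-quartile scaling the calls were 732 higher and 736 lower, so that the excess of raised genes depends on the scaling. Without Detroit 562 control replicate 1 there were 762 calls, and without control replicate 3 there were 884.

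EGFR ligands and MAPK feedback genes, a list that also holds receptor genes such as EGFR, ERBB2 and MET, formed the most responsive list in Detroit 562 by camera. Of its 27 genes 12 rose and 1 fell, or 13 and 2 adjusted over the list alone. The AP-1 gene FOSL1 rose by 0.53, the early response gene IER3 by 0.62, the EGFR ligand gene TGFA by 0.70 and the ERK phosphatase gene DUSP6 by 0.68, and EGFR itself fell by 0.26. The list was higher (adjusted p = 9.24e-05, and adjusted p = 0.0933 with an estimated correlation). DUSP6 and IER3 overlap antisense genes over 36.4% and 26.1% of their exons, as do IER2 over 29.5% and DDIT4 over 44.1%, so that their values are uncertain. Of 20 immediate early and heat shock genes, EGR1, IER2 (0.79), JUN (0.30) and the mitochondrial chaperonin gene HSPD1 (0.20, with 24.8% of its exon sequence shared) rose, or 4 rose and 1 fell adjusted over the list alone (list higher, adjusted p = 0.0188, and adjusted p = 0.158 with an estimated correlation). The call of JUN was lost without Detroit 562 control replicate 1 (adjusted p = 0.125). Among 42 hypoxia and glycolysis genes 7 rose, or 10 adjusted over the list alone (adjusted p = 0.0115, and adjusted p = 0.271 with an estimated correlation). They included the mTORC1 inhibitor gene DDIT4 (0.40), the phosphofructokinase gene PFKL (0.35), the angiogenic ligand gene VEGFA (0.26) and the lactate transporter gene SLC16A3 (0.33). Of 40 unfolded protein and stress response genes 9 rose and 1 fell, or 11 and 1 adjusted over the list alone (list higher, adjusted p = 0.0118, and adjusted p = 0.159 with an estimated correlation); TRIB3 rose by 0.43 and DNAJC3 fell by 0.59.

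Further lists were lower in Detroit 562. YAP/TAZ targets gave 8 fallen and 5 risen of 27, or 8 and 6 adjusted over the list alone (adjusted p = 0.000867, and adjusted p = 0.271 with an estimated correlation). F3 fell by 0.66 and FJX1 by 0.57, while CCN1, a matricellular integrin ligand gene, rose by 0.41. NRF2 targets gave 7 fallen and 1 risen of 39, and the same counts adjusted over the list alone (adjusted p = 0.00169, and adjusted p = 0.349 with an estimated correlation). TXNRD1 fell by 0.41, the glutathione synthesis gene GCLC by 0.35 and the glutathione reductase gene GSR by 0.28. TXNRD1 and GCLC held AAGACTA in the 3′ UTR, and GSR held none of the sequences found in lowered genes. Of 40 homologous recombination and crosslink repair genes 5 fell, or 8 adjusted over the list alone (adjusted p = 0.0115, and adjusted p = 0.349 with an estimated correlation). The double-strand break sensor gene NBN (-0.22), the polymerase theta gene POLQ (-0.24), FANCD2 (-0.20) and RAD54B (-0.20) were among them, and each lost its call without Detroit 562 control replicate 1 (adjusted p = 0.0671, 0.116, 0.0821 and 0.159). The calls of POLQ, FANCD2 and RAD54B were also lost without control replicate 3 or THBS1 siRNA replicate 1, and those of FANCD2 and RAD54B without control replicate 2 or THBS1 siRNA replicate 3. RAD54B shares 78.9% of its exon sequence with FSBP, so that its value is uncertain. In the 3′ UTR, NBN held AAGACTA and AGACTAA and FANCD2 held ACAACGA, while POLQ and RAD54B held none of the sequences found in lowered genes. Among 17 thrombospondins and receptors, SDC4 (0.63), SDC1 (0.26) and the calreticulin gene CALR (0.20) rose and THBS1 fell, with the same counts adjusted over the list alone. The call of CALR was lost without control replicate 1 (adjusted p = 0.0768) or THBS1 siRNA replicate 3 (adjusted p = 0.121). That list was lower by camera (adjusted p = 0.00455, and adjusted p = 0.0933 with an estimated correlation) owing to THBS1 itself, and without THBS1 it was not called by camera (adjusted p = 0.0722, median 0.06) and was higher by fry (adjusted p = 0.000729).

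The remaining lists were not called by camera in Detroit 562. Fry called 5 of them, namely mesenchymal transition (adjusted p = 0.00134), apoptosis regulators (0.0122) and stemness (0.0461), all higher, and interferon-stimulated genes (0.0450) and canonical histones (0.0265), lower. TGF-beta response genes gave 2 risen and 3 fallen of 30 (5 and 5 adjusted over the list alone), with COL4A1 at -0.78. Matrix and integrin genes gave 6 and 3 of 38 (6 and 4), with the integrin gene ITGB8 at -0.49. Mesenchymal transition genes gave 3 and 1 of 27 (3 and 2), epithelial junction genes 1 and 1 of 30 (1 and 1), namely CLDN4 (0.19) and DSG2 (-0.23), and squamous differentiation genes 1 and 2 of 33 (1 and 2), with the keratin gene KRT4 at -0.44 and EMP1 at 0.24. End joining and damage signalling genes gave 2 and 3 of 40 (2 and 4), with the checkpoint kinase gene WEE1 at -0.38 and the checkpoint clamp gene RAD1 at -0.26. Other repair genes gave 2 and 2 of 34 (2 and 2), with TDG at 0.30, and p53 targets 2 and 3 of 31 (2 and 3), with CCNG1 at -0.59 and GADD45A at -0.32. Of 39 G1/S genes RRM2 (-0.33) and CCNE2 (-0.71), which overlaps an antisense gene over 48.2% of its exons, fell (2 adjusted over the list alone), and of 42 G2/M genes 3 rose and 3 fell (3 and 3), with the phosphatase gene CDC25A at 0.41. Interferon-stimulated genes gave 5 fallen of 46 (5), with IFIT2 at -0.30. Antigen presentation genes gave 3 risen and 1 fallen of 27 (3 and 1), with CD274, the gene of PD-L1, at 0.60 (adjusted p = 0.0585 without control replicate 1). NF-kappaB and cytokine genes gave 6 and 2 of 38 (6 and 2), with the cyclooxygenase gene PTGS2 at 0.38 and IL1B at 0.39. Lipid synthesis genes gave 2 and 2 of 34 (2 and 2), with ELOVL6 at -0.77. Angiogenesis genes gave 3 and 3 of 26 (4 and 3), with TIMP3 at -0.65 and JAG1 at -0.32. PI3K, AKT and mTOR components gave 1 and 5 of 31 (1 and 5), with AKT1 at 0.32 and PIK3R3 at -0.63 (25.1% of its exon sequence is shared). Apoptosis regulators gave 5 and 2 of 36 (5 and 3), with the survival gene BCL2L2 at 0.30. Of 21 stemness genes 3 rose (4 adjusted over the list alone), of 22 canonical histone genes H2BC5 (0.48) rose and H2AC11 (-0.63) fell (1 and 1), and of 13 mitochondrially encoded messengers MT-ND5 (0.27) and MT-ND6 (0.23) rose (2 adjusted over the list alone). Calls lost without Detroit 562 control replicate 1 included those of CLDN4 (adjusted p = 0.449), H2BC5 (adjusted p = 0.178) and MT-ND6 (adjusted p = 0.220). Others were those of HLA-E and CD276, of MMP14 and ITGA5, and of XPC (which overlaps an antisense gene over 28.6% of its exons), PMS1, DDB2, HUS1, TNFRSF10A, PIK3CB and PIK3R1. All 3 stemness calls, NGFR, SOX9 and MYC, were also lost. NLRC5 lost its call in 3 other fits that left out 1 library (adjusted p up to 0.544). DESeq2 called 1 stemness and 2 antigen presentation genes. CLDN4 also lost its call without THBS1 siRNA replicate 1 or 2, MT-ND5 without THBS1 siRNA replicate 3 (adjusted p = 0.0997), and MT-ND6 without any 1 library but THBS1 siRNA replicate 1. Of the fallen genes named in these lists, COL4A1, ITGB8, DSG2, RAD1, RRM2, CCNE2, ELOVL6 and PIK3R3 held at least 1 of the sequences found in lowered genes. KRT4, WEE1, CCNG1, GADD45A, IFIT2, TIMP3, JAG1 and H2AC11 held none. Markers of other cell types were few in either line. None of 4 fibroblast, 6 endothelial and 3 leukocyte markers was called by edgeR or DESeq2 in either knockdown comparison, and in Cal27 1 endothelial and 1 leukocyte marker had an unadjusted p under 0.05, against 0 in Detroit 562.

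Whether the lines responded differently was tested as the difference between their knockdown effects. EGR1 rose in Detroit 562 and not detectably in Cal27 (0.02 ± 0.069 SE), a difference of 1.09 ± 0.126 SE (adjusted p = 1.20e-05). The small MAF transcription factor gene MAFF rose by 0.62 in Detroit 562 and fell by 0.45 in Cal27 (difference 1.07 ± 0.152 SE, adjusted p = 0.000208). DUSP6 differed by 0.76 ± 0.112 SE (adjusted p = 0.000295), IER3 by 0.54 ± 0.077 SE (adjusted p = 0.000208) and FOSL1 by 0.48 ± 0.068 SE (adjusted p = 0.000152). NOLC1 rose more in Detroit 562 (difference 0.69 ± 0.071 SE, adjusted p = 1.89e-06), and RBM28 and NCBP1 fell further there (differences -0.56 ± 0.089 SE and -0.52 ± 0.071 SE). In the other direction CYP1B1, a cytochrome P450 gene induced by the aryl hydrocarbon receptor, rose by 0.93 in Cal27 and by 0.27 in Detroit 562 (difference -0.67 ± 0.102 SE, adjusted p = 0.000459).

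Among EGFR ligands and MAPK feedback genes, 7 of 27 had a higher log2 fold change in Detroit 562 than in Cal27, or 12 adjusted over the list alone. Besides DUSP6, IER3 and FOSL1 these were the ETS factor gene ETV5 (0.67), TGFA (0.42), PHLDA1 (0.39) and CCND1 (0.27). The list was higher (camera adjusted p = 1.76e-20), and of all list tests of the difference it alone was called with an estimated correlation (adjusted p = 0.00130). YAP/TAZ targets, lower as a list in both lines, fell less in Detroit 562, with a median of -0.045 against -0.126 in Cal27. Camera called this difference (adjusted p = 2.78e-06, and adjusted p = 0.140 with an estimated correlation). CCN1 (0.49) and F3 (0.32) were called, and 6 were higher and 1 lower adjusted over the list alone. NRF2 targets had a lower log2 fold change in Detroit 562 (adjusted p = 6.62e-07, and adjusted p = 0.140 with an estimated correlation). The glutathione peroxidase gene GPX2 (-0.56) was called, and 4 were lower adjusted over the list alone. Hypoxia genes (adjusted p = 0.00349, and adjusted p = 0.256 with an estimated correlation), with DDIT4 (0.38) called and 3 adjusted over the list alone, were higher. So were immediate early and heat shock genes (adjusted p = 0.00888, and adjusted p = 0.140 with an estimated correlation), where EGR1 was called and 2 genes adjusted over the list alone. Lists of G2/M genes (adjusted p = 0.00349, and adjusted p = 0.430 with an estimated correlation) and angiogenesis genes (adjusted p = 0.0205, and adjusted p = 0.152 with an estimated correlation) were higher. Fry also called the lists of EGFR ligands and MAPK feedback (adjusted p = 0.00012), YAP/TAZ targets (0.0249) and immediate early and heat shock genes (0.0443), but not those of G2/M (0.116), hypoxia (0.0763), NRF2 (0.0940) and angiogenesis genes (0.0557). No member of the G2/M or angiogenesis list was called by edgeR or DESeq2, with 4 at an unadjusted p under 0.05 in each, and 0 and 1 adjusted over the list alone.

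Further genes with a higher log2 fold change in Detroit 562 than in Cal27 were ELFN2 (0.72), the semaphorin gene SEMA7A (0.70), CHORDC1 (0.30), the TGF-beta feedback gene PMEPA1 (0.43), PLK2 (0.33), MT-ND5 (0.53) and MT-ND6 (0.47). CHORDC1 and PLK2 fell less there than in Cal27. The retinol dehydrogenase gene RDH10 (-0.48), the nucleoside transporter gene SLC29A3 (-0.47) and HEATR5B (-0.41) had a lower log2 fold change in Detroit 562. In all 38 genes were called, 30 higher and 8 lower. With the replicate block 26 were higher and 4 lower, and with DESeq2 23 were higher and 4 lower. The count of 38 moved to 84 without Cal27 control replicate 2 and to 24, 23, 25 and 21 without Cal27 THBS1 siRNA replicate 2, its replicate 3, Detroit 562 control replicate 1 and its replicate 3. When 1 library was left out, the calls of SEMA7A (adjusted p = 0.0744 without Detroit 562 control replicate 3), F3 (up to 0.0915), ETV5 (up to 0.113), RDH10 (up to 0.142), PLK2 (up to 0.0842), GPX2 (up to 0.199), MT-ND6 (up to 0.199), CHORDC1 (up to 0.287), ELFN2 (up to 0.361), SLC29A3 (up to 0.415), HEATR5B (up to 0.181), TGFA (up to 0.247) and CCND1 (up to 0.135) were lost in at least 1 fit, while those of EGR1, MAFF, DUSP6, IER3, FOSL1, PHLDA1, NOLC1, RBM28, NCBP1, CYP1B1, CCN1, DDIT4, PMEPA1 and MT-ND5 held in each. With DESeq2 the calls of MT-ND5 (adjusted p = 0.0601), MT-ND6 (adjusted p = 0.373), ELFN2, ETV5, HEATR5B, RDH10, SLC29A3 and TGFA for the difference were lost.

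**Figure D4:**
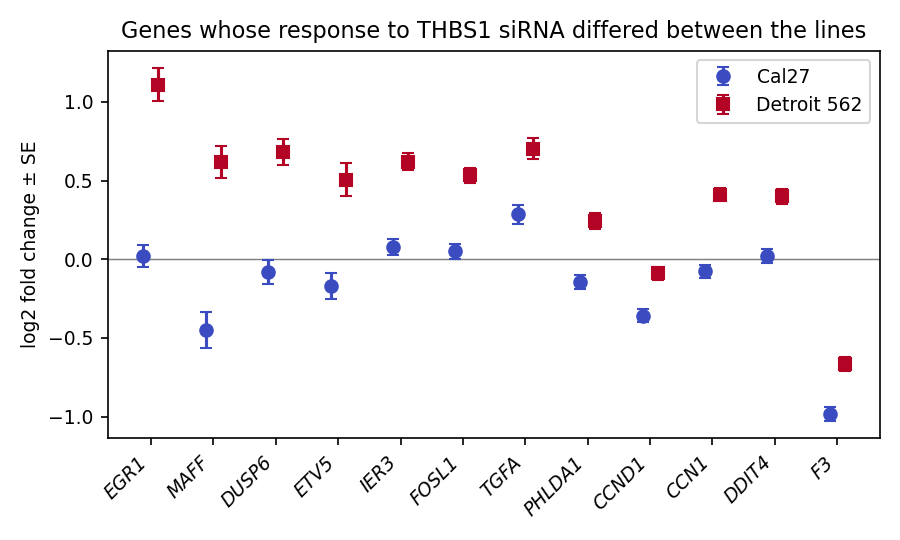
Log2 fold change after THBS1 siRNA (vertical axis) with its SE for 12 genes whose response differed between the lines, in Cal27 (circles) and Detroit 562 (squares). EGR1 lies at 0.02 in Cal27 and 1.11 in Detroit 562, and DUSP6 at -0.08 and 0.68.

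The lines themselves were compared with control siRNA, where the culture medium differed along with the line. Detroit 562 expressed the mucin-type glycosyltransferase gene GALNT5 (ENSG00000136542) at 158 ± 15.3 CPM, at least 4169-fold higher than Cal27, which had no count in 3 libraries. The same bound, with a floor of 3 counts over the group, was at least 2246-fold for the oligosaccharyltransferase gene TUSC3, 924-fold for the RNA-binding protein gene CELF2 and 597-fold for the phosphodiesterase gene PDE9A. The imprinted genes PEG10 and SGCE were higher by ratios of 25444 (95% counting interval 4566 to 1005050) and 3407 (942 to 28139). The tight junction gene CLDN11 stood at 531.6 ± 10.2 CPM against 0.0740 ± 0.0976 in Cal27 (25.5% of its exon sequence is shared with another gene), and the vitamin D hydroxylase gene CYP24A1 at 849.8 ± 24.7 against 0.292 ± 0.110.

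Cal27 expressed the basal keratin gene KRT14 at 1071 ± 114 CPM, against 0.174 ± 0.198 in Detroit 562 (23.8% of its exon sequence is shared with KRT16), and SPARC, a secreted collagen-binding protein gene, at 514.1 ± 10.9 CPM, a ratio of 7541 (2580 to 36568). The inflammasome-related gene NLRP2 was higher by a ratio of 5202 (933 to 205478). FILIP1L was at least 361-fold, LRRC61 343-fold, RCSD1 258-fold and the homeobox gene ALX4 242-fold higher. MAGEA3, a cancer-testis antigen gene, was at least 1873-fold higher but shares 58.2% of its exon sequence with MAGEA6. Lower bounds on the Detroit 562 side rest largely on control replicates 1 and 3, given the depth of replicate 2.

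Squamous differentiation genes were lower in Detroit 562 in 23 of 33 cases and higher in 7 (camera adjusted p = 0.0150), with the basal keratin gene KRT15 at -6.93 and the kallikrein gene KLK5 at -9.57. Interferon-stimulated genes were lower in 38 of 46 and higher in 5 (adjusted p = 6.69e-06), with IFI27 at -6.26 and the tetherin gene BST2 at -5.15. G2/M genes were lower in 27 of 42 and higher in 10 (adjusted p = 0.0125), with the topoisomerase gene TOP2A at -1.12. In contrast YAP/TAZ targets were higher in 24 of 27 and lower in 3 (adjusted p = 8.14e-06), with ANKRD1 at 7.71 and YAP1 itself at 2.95. TGF-beta response genes were higher in 23 of 30 and lower in 5 (adjusted p = 4.06e-05). NF-kappaB and cytokine genes were higher in 25 of 38 and lower in 9 (adjusted p = 0.0147), with PTGS2 at 6.19, and angiogenesis genes higher in 19 of 26 and lower in 4 (adjusted p = 0.00242), with the semaphorin gene SEMA3F at 3.86. Counts adjusted over the list alone were the same for these 7 lists, and each of the 7 list tests had an adjusted p = 0.523 with an estimated correlation. Fry called 23 further lists between the lines. Other large differences were the adhesion receptor gene CD44 (3.03), the receptor kinase gene MET (2.57), fibronectin FN1 (3.53) and tenascin TNC (-4.40). Of 13346 genes 11054 were called, 5431 higher and 5623 lower, and 4104 differed at least 2-fold. With no low-count filter 5766 were higher and 5679 lower.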

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

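The tests of whether 7-base sequences take part in the shared changes, and the counts of lowered and of raised calls among genes with no 6-base match, were chosen only after the results had been seen.

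Genes lowered in both lines (305, or 304 besides THBS1) were weighed first. A candidate explanation for part of them is seed pairing of the THBS1 siRNA with other messengers. AAGACTA, which ranked first in Cal27 with t = -9.89, had t = -6.76 in Detroit 562 against a lowest value of -4.93 in permutations. Genes with AAGACTAA were lower than genes with only 1 of its 7-base parts by a median log2 of -0.060 (one-sided permutation p = 1e-05, the smallest that 100000 resamples can give). The parts of AAGACTAA were picked on these same fold changes, and this comparison was not adjusted for UTR length, GC content or expression. Its p value is therefore no separate test of seed pairing. AAGACTA occurs in the THBS1 messenger, first in its coding sequence at chromosome 15, 39590550 to 39590556, though 33.8% of the sequences tested also occur there and the siRNA sequence was not known. The share set beforehand for a whole cause was met, since 89.1% of the lowered genes had a 6-base match anywhere in the messenger, against 53.3% of all. Genes with no such match still shared 33 lowered calls against 2.22 for independent lists, a ratio of 14.9. That argues against direct matches in the transcripts searched as the whole cause, while other transcripts of these genes were not searched. An effect of THBS1 loss itself, and effects downstream of other lowered genes, stay open and were not tested, since each line had 1 THBS1 siRNA reagent and no rescue.

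For genes raised in both lines (440), the same question was put to the control siRNA, whose targets would appear raised once it is replaced. CGGAGAA, first in Cal27 with t = 7.25, had t = 8.05 in Detroit 562 against a highest value of 5.09 in permutations. Genes with TCGGAGAA were higher than genes with only 1 of its parts by a median log2 of 0.090 (one-sided permutation p = 0.00048). Those parts, too, were picked on these same fold changes and compared without adjustment, so that this p value is no separate test. Seed pairing of the control siRNA may account for part of the raised genes. Matches to CGGAGA in the transcripts searched are argued against as the whole cause: 73.9% (95% Wilson interval 69.6 to 77.8%) of the raised genes had this 6-base match, against 42.4% of all, and 115 genes without it were shared against 8.47 for independent lists, a ratio of 13.6. Related sequences without CGGAGA also passed the Detroit 562 limit, namely GGAGAAA (t = 6.17), TGGAGAA (6.16) and AAGGAGA (5.64). In Cal27 their t values were 5.11, 4.82 and 3.07, within the limit of 5.12. Genes that hold these related sequences were not set aside. With genes that hold AGACTA, CAACGA or CGGAGA set aside, 92 genes of 3849 were still shared in the same direction against 7.47, a ratio of 12.3. Matches to these 6-base sequences in the transcripts searched are thus argued against as the whole source of the agreement between the lines. The siRNA sequences were not known, so that matches to other parts of them were not set aside. An effect of THBS1 loss stays open for these genes too.

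The higher log2 fold change of EGFR ligands and MAPK feedback genes in Detroit 562 was weighed because the difference itself was called, with a list median of 0.30. The shallow control library is argued against, since 7 of the 7 called genes kept their call without it and their median difference moved from 0.481 to 0.478. Direct pairing of the control siRNA with these genes through 7-base matches in the 3′ UTR is argued against, with 0 of the 7 holding TCGGAGA or CGGAGAA. Of all tested genes 3.55% held either sequence, and of those raised in both lines 17.9%. Shorter matches and matches elsewhere in the messenger were not counted for the 7 genes. DUSP6 and PHLDA1 held AAGACTA and AGACTAA, and the other called genes of the list held neither. Pairing of the THBS1 siRNA with the called genes was not tested. The median log2 fold change of 10 heat shock genes in Detroit 562 was -0.0058 (interquartile range 0.090), against 0.53 for the 7 genes. That argues against a heat shock response. The called immediate early genes EGR1, IER2 and JUN rose there, so that another response to handling stays open. Indirect effects of either siRNA through other genes, and a difference between the lines in the response to THBS1 loss, stay open. They were not tested, since each line had 1 THBS1 siRNA reagent and the culture medium goes with the line.

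The test of the difference also called single genes. EGR1 differed by 1.09, MAFF by 1.07, DUSP6 by 0.76, ELFN2 by 0.72, SEMA7A by 0.70, NOLC1 by 0.69 and ETV5 by 0.67 (log2, Detroit 562 minus Cal27). IER3 differed by 0.54, MT-ND5 by 0.53, CCN1 by 0.49, FOSL1 by 0.48, MT-ND6 by 0.47, PMEPA1 by 0.43, TGFA by 0.42, PHLDA1 by 0.39 and DDIT4 by 0.38. PLK2 differed by 0.33, F3 by 0.32, CHORDC1 by 0.30 and CCND1 by 0.27. Genes with a lower log2 fold change in Detroit 562 than in Cal27 were CYP1B1 (-0.67), RBM28 (-0.56), GPX2 (-0.56), NCBP1 (-0.52), RDH10 (-0.48), SLC29A3 (-0.47) and HEATR5B (-0.41). Of these, RBM28 and NCBP1 fell further in Detroit 562. List tests of the difference were called for G2/M genes (median 0.053), hypoxia genes (0.078), NRF2 targets (-0.11), YAP/TAZ targets (0.13), angiogenesis genes (0.14) and immediate early and heat shock genes (0.068).

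Other splits of the same libraries were counted beside each result. Most of them mixed the arms, or the lines, within a group, so that a real effect widened the spread there and lowered the counts. For the 745 genes shared in the same direction, 1 of 100 splits, the real one, gave as many, and the highest of the others gave 5. That share is under the 0.05 set beforehand, but it does not exclude chance. For the 38 genes that differed between the lines, 9 of 100 splits gave as many, the highest other being 2425 with the arms of 1 line swapped, so that by this count chance cannot be excluded. All 8 of the other such splits kept 1 line at its real grouping, and the 85 splits with neither line at its real grouping gave at most 1 gene, which points to the knockdown effect itself as the structure behind the large counts. For the calls in Cal27 (1331, highest other 1), in Detroit 562 (1465, highest other 0) and between the lines (11054, highest other 0), the 10 splits are too few for a share under 0.05, and 1 split, the real one, gave as many in each.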

How the results depend on the processing

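Fits without both doubted libraries, Cal27 calls without the shallow library, the fits of 7-base sequences on other fold changes, and list tests without THBS1 in its list were chosen only after the data had been seen. THBS1 kept its direction and its side of the threshold in both lines under every alternative run, with log2 fold changes of -2.61 to -2.68 in Cal27 and -2.66 to -2.71 in Detroit 562 when 1 library was left out. With 1 library left out, calls ranged from 959 to 1403 in Cal27, 762 to 1415 in Detroit 562, 21 to 84 for the difference between the lines, 493 to 776 shared and 10512 to 11137 between the lines; with fewer libraries the spread is less well known, and the cause of single shifts was not tested. Without both doubted libraries the difference between the lines gave 22 calls in place of 38, all of them among the 38, with fewer samples in the fit. The other alternatives left these counts within 1.5 times, including DESeq2 (911, 992, 27, 556 and 10458) and the replicate block (1256, 1265, 30, 660 and 11078). Upper-quartile factors moved the median between the lines from -0.03 to -0.10 and turned the excess of raised genes in Detroit 562 from 894 and 571 into 732 and 736; in Cal27 they gave 656 raised and 745 lowered, and no low-count filter gave 616 and 765. Of 5241 alternative values for 365 named gene results, 4887 kept direction and side of the threshold, 354 kept direction and lost the call, and 0 reversed. The t values of the 4 sequences AAGACTA, AGACTAA, TCGGAGA and CGGAGAA stayed beyond the permutation limits in both lines with upper-quartile factors, DESeq2 fold changes and without both doubted libraries, the nearest to 0 being 6.13 for TCGGAGA in Cal27. Without THBS1 the list of thrombospondins and receptors turned from lower to higher, with no camera call in Cal27 (adjusted p = 0.0931) and Detroit 562 (adjusted p = 0.0722) but a fry call in both (adjusted p = 0.00186 and 0.000729), since the siRNA target had made it lower, and angiogenesis genes in Cal27 lost their call (adjusted p = 0.0548), as the correction over lists changed. An estimated correlation ended 4 list calls in Cal27, 8 in Detroit 562, 6 for the difference and 7 between the lines, and fry added 6, 5, 0 and 23 and ended 4 for the difference. Depth limits genes near 3.80 CPM in Detroit 562 control replicate 2.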

Other observations

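The tests reported in this part were chosen only after the results had been seen.

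A second pair of 7-base sequences, ACAACGA and CAACGAA, was present in the 3′ UTR of 32 of the 304 genes lowered in both lines (10.5%, 95% Wilson interval 7.56 to 14.5%), against 1.62% of the raised genes and 2.30% of all genes tested. In Detroit 562 the t values were -5.78 and -5.67, beyond the lowest of the permutations, and in Cal27 they were -4.56 and -2.54, within it. The 58 genes with ACAACGAA had a median log2 fold change of -0.09, against -0.04 for 241 genes with only 1 of its parts and 0.00 for genes with neither (one-sided permutation p = 0.00378). These parts were likewise picked on these same fold changes and compared without adjustment, so that this p value is no separate test. ACAACGA occurs in the THBS1 coding sequence at chromosome 15, 39592731 to 39592737, while CAACGAA does not occur in the THBS1 messenger. No 7-base sequence passed the permutation limits for the difference between the lines, where the lowest t was -3.50 and the highest 3.86, against limits of -4.97 and 5.02.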
